A study of Drosophila melanogaster with 4 samples.

How the data were processed

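H3K9me2 ChIP-seq of Oregon-R embryos was analysed from 3 deposited cluster lists, 1 for each of the 2 ChIP replicates and 1 for the replicate set. Per the labels, each ChIP replicate had its own input library, and the 2 inputs enter here only through the authors' enrichment calls. Embryos were fixed with formaldehyde and chromatin was immunoprecipitated on beads before DNA purification, per the labels' protocols. Reads were processed with Bowtie 0.12.7 among the tools, per the submitters' processing notes. The genome build was FlyBase release 5, per the file headers, which also give the length of each sequence. The cluster caller, its threshold, the read filters and the way the replicates were combined in the pooled list are not given in the sources used here.

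Each row of a list is a cluster of significant enrichment with a start, an end and a score, as deposited by the authors. The scale of this score is not stated in the headers or labels. It was examined in the values: among scores that occurred in more than 1 cluster, 28.8% in replicate 1, 20.9% in replicate 2 and 27.7% in the pooled list were related to the highest such score by a ratio of whole numbers (denominator at most 100, relative tolerance 1e-06) when 2 was taken as the base of the logarithm. With base e no score, and with base 10 at most 0.685%, met this criterion. The score therefore appears to be on a log2 scale of a count ratio, but the base is inferred. It was used to rank clusters within a list, as it stands in Pearson's r between the replicates, and as a log2 value in 2 tests of the closing section. No read counts were used here, so the depth behind each cluster and each library is unknown and no confidence interval based on reads is given. A stricter threshold or a shallower library shortens a list, so covered shares and scores of different lists are not comparable in level.

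Clusters that ran past the stated end of a sequence were trimmed there, which affected 3 clusters in each replicate and 5 in the pooled list. No cluster lay on sequence Uextra, which is 29.0 Mb long, and whether reads could be placed there is not known. Clusters were compared as base pair intervals with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the Jaccard index was checked against bedtools 2.31.1. The covered share of a region is its covered length divided by its length in the headers. This length was not corrected for assembly gaps or for sequence where reads cannot be placed, which were not assessed here. The proximal end is the right end of X, 2L and 3L and the left end of 2R and 3R, and the proximal part is the last 1 Mb before it. It is an end of the release 5 arm sequence, so the Het sequences assembled apart are not part of the proximal 1 Mb. The rest of each of these 5 arms is called distal. Windows of 100 kb were used for profiles.

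Chance values came from 1000 circular rotations of the clusters within each sequence with a fixed seed, which keep cluster lengths and spacing but remove the position along the sequence. Rotation p-values are one-sided. Clusters of 2 lists were counted as shared when they overlapped by at least 1 bp. For the scores, each replicate 1 cluster was paired with the replicate 2 cluster of largest overlap, and p-values came from 100000 permutations of the pairing with Benjamini-Hochberg adjustment over 7 sets of pairs. These procedures were tested on simulated clusters. Lists made to share 50% of their clusters gave 50%, a proximal ratio made as 10 gave 10.2, and of 100 unrelated simulations 3% of pairs and 4% of lists had a p at or under 0.05. A first version of the simulation placed clusters on a regular lattice, gave too many small p-values among unrelated lists, and was replaced by one with random gaps. The unrelated lists held 1500 clusters of equal length spread at random over the 5 arms, with fewer than 1000 rotations. They lacked the long dense blocks of the real lists, so these rates do not cover such blocks.

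Regions were named by a rule fixed before the data were examined: on each arm and on chromosome 4, the longest pooled cluster touched by both replicates and the highest-scoring one outside the proximal 1 Mb. The tests, the 1 Mb window and the alternatives described in the closing section were also fixed before the data were examined, except where stated. Gene groups and the exon, intron and intergenic shares had been planned for the case of a matching annotation. The gene table at hand is of release 6, so genes were not analysed here. With 2 ChIP libraries of 1 condition no test between groups of samples was made.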

Results

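Chromatin from wild-type Oregon-R embryos of Drosophila melanogaster, 14 to 16 h old, was immunoprecipitated with an antibody against histone H3 dimethylated at lysine 9 (H3K9me2), a modification characteristic of heterochromatin. The immunoprecipitated DNA was sequenced. The labels name 4 samples, which are 2 H3K9me2 ChIP libraries and the 2 input libraries that served as their references, and they describe the antibody as a new lot. The labels do not say whether the ChIP replicates came from separate embryo collections, so the SDs given here measure only the spread between these samples, which may be technical. Replicate 1 held 3579 clusters of significant enrichment, which covered 23.6 Mb. Replicate 2 held 3238 clusters, which covered 21.6 Mb. The authors' list for the replicate set, called the pooled list here, held 4277 clusters over 27.0 Mb. The lists give positions and scores but no read counts, so the sequencing depth behind each cluster is unknown. Because only whole embryos of 1 stage were profiled, with 1 antibody, the comparisons are between chromosome regions, between the replicates, and between the replicates and the pooled list.

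Clusters covered most of the assembled heterochromatin and little of the euchromatic arms. The Het sequences of FlyBase release 5, which are mapped pieces of heterochromatin assembled apart from the arms, were covered over 74.6% ± 1.06 (SD, n = 2). Sequence U, which joins scaffolds of no assigned chromosome, was covered over 74.1% ± 2.18 (SD, n = 2). Arm X was covered over 9.22% ± 1.69 and the autosomal arms 2L, 2R, 3L and 3R together over 5.70% ± 0.668 (SD, n = 2). Among the Het sequences, 3LHet had the highest covered share, 82.1% ± 1.16, followed by 3RHet with 77.7% ± 0.508 and YHet with 71.5% ± 0.751 (SD, n = 2). The shares of 2RHet and 2LHet were 69.8% ± 1.53 and 67.9% ± 1.33. XHet, only 0.204 Mb long, was covered over only 37.5% ± 0.709 in the separate lists (SD, n = 2), and over 51.5% in the authors' pooled list. Each difference between the Het sequences and the arms was many times the spread between replicates, but no test across the 2 libraries was made. With only the upper 50% of each list by score, the mean covered share was 3.42% of the autosomal arms and 2.98% of X, while that of the Het sequences was 70.3%.

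**Figure D1:**
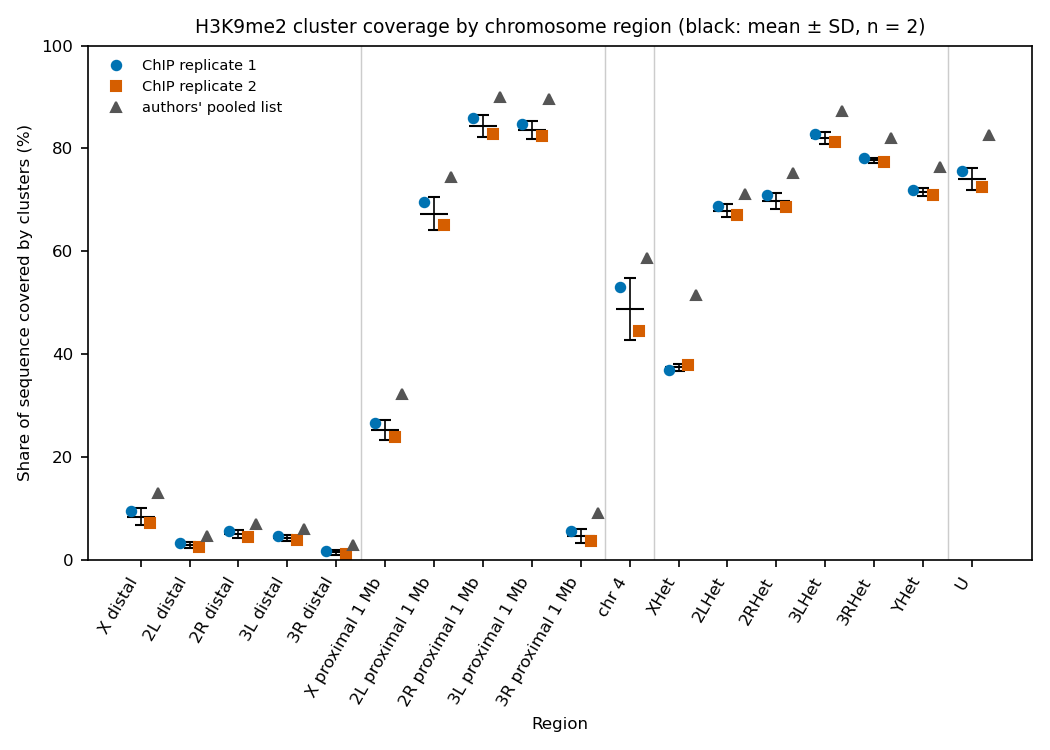
Share of each region covered by H3K9me2 clusters, in percent, for ChIP replicate 1, ChIP replicate 2 and the authors' pooled list, with the black bars giving the mean ± SD of the 2 replicates. The distal parts of the arms sit below 15%, the Het sequences other than XHet and sequence U sit above 65%, and chromosome 4 lies between them at 48.8%.

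As a group, the clusters of the Het sequences were longer and scored higher than those of the arms. The median cluster on the Het sequences was 8.06 kb long in replicate 1 and 7.29 kb in replicate 2. On the 5 large arms the medians were 2.19 kb and 2.33 kb. XHet was an exception in length, with medians of 2.00 kb over 11 clusters and 1.88 kb over 15 clusters. The longest replicate clusters lay on 2RHet, with 120 kb in replicate 1 and 123 kb in replicate 2, and the longest pooled cluster lay on 3RHet and spanned 147 kb. Median scores, which are the authors' own values and are compared only within a list, were 2.10 on the Het sequences, 2.62 on U and 0.757 on the 5 arms in replicate 1. The corresponding medians in replicate 2 were 2.32, 2.89 and 1.05.

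Within the arms, clusters were concentrated at the centromere-proximal ends of 2L, 2R and 3L. The proximal 1 Mb of 2R was covered over 84.3% ± 2.21, that of 3L over 83.6% ± 1.70 and that of 2L over 67.3% ± 3.18 (SD, n = 2). The remainders of these arms were covered over 5.12% ± 0.755, 4.32% ± 0.645 and 2.94% ± 0.599 (SD, n = 2). The proximal ends of X and 3R differed from these, with 25.3% ± 1.98 and 4.77% ± 1.36 (SD, n = 2). These values describe the arm sequences only and depend on where each arm sequence ends. The 2.52 Mb of 3RHet, assembled apart from arm 3R, were covered over 77.7%. Counted outward from the proximal end in 100 kb windows, an unbroken run of windows covered over at least 50% reached 1.6 Mb on 2R in replicate 1 and 1.5 Mb in replicate 2. The run reached 1.5 Mb on 3L and 0.8 Mb on 2L in both replicates, and no such run began on X or 3R. This window rule was chosen after the data were examined.

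Over the 5 arms together, the covered share of the proximal 1 Mb was 12.5 ± 1.85 times that of the rest (SD, n = 2), with ratios of 11.2 in replicate 1 and 13.8 in replicate 2. Permutation by circular rotation of the clusters within each arm gave a mean ratio of 1.06 and a highest ratio of 7.51 in 1000 rotations (one-sided p = 0.001, the smallest that 1000 rotations can give). The ratio for single arms ranged in replicate 1 from 2.76 on X and 3.10 on 3R to 15.2 on 2R, 17.8 on 3L and 20.7 on 2L. In replicate 2 these ratios were 3.28, 3.19, 18.1, 21.3 and 25.9. With the upper 50% of each list by score, the ratio over the 5 arms was 32.1.

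**Figure D2:**
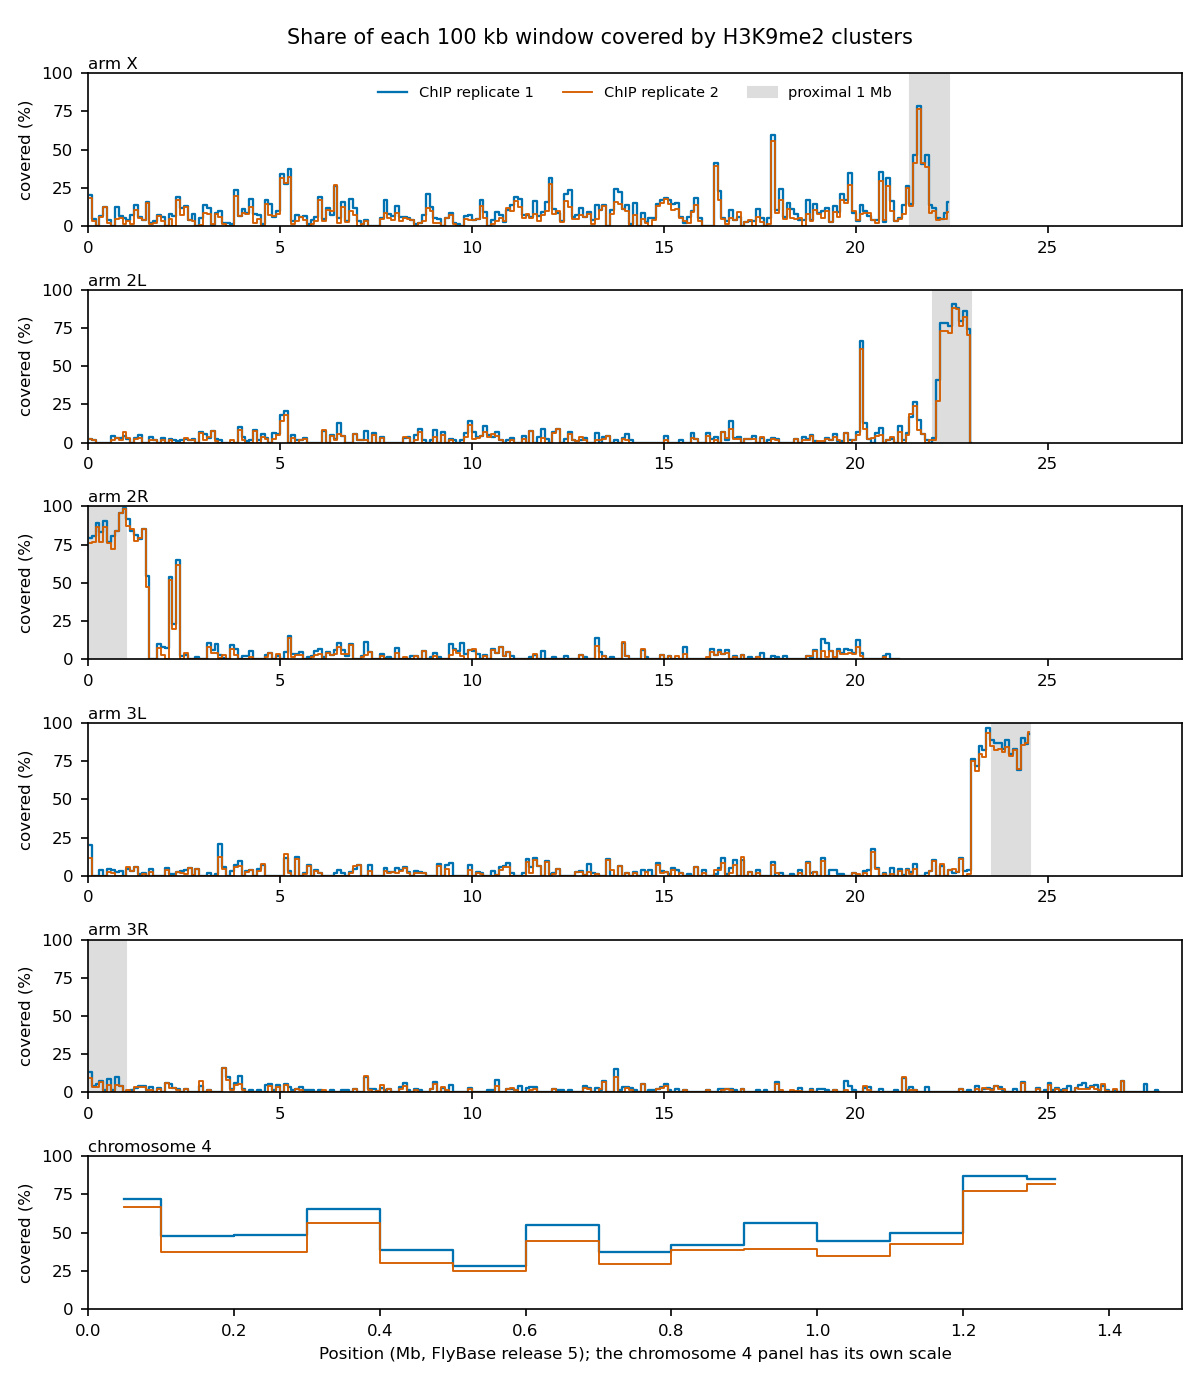
Share of each 100 kb window covered by H3K9me2 clusters, in percent, along the 5 large arms and chromosome 4 in FlyBase release 5 coordinates in Mb, with 1 line per ChIP replicate and grey shading over the proximal 1 Mb. Both replicates show a block at the proximal end of 2L, 2R and 3L, no block on 3R, and many partly covered windows along X.

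Chromosome 4, a small chromosome that is largely heterochromatic yet carries active genes, had an intermediate covered share. Clusters covered 53.1% of it in replicate 1 and 44.5% in replicate 2, a mean of 48.8% ± 6.05 (SD, n = 2), against 58.7% in the authors' pooled list. This was 11.4 ± 0.724 times the covered share of the distal parts of the 5 large arms, which are the arms without their proximal 1 Mb (SD, n = 2). The 14 windows of chromosome 4 were covered unevenly. The window from 500001 to 600000 had the lowest share, 28.4% in replicate 1 and 24.8% in replicate 2. The last, shorter window from 1300001 to 1351857 had the highest mean of the replicates, with 85.2% in replicate 1 and 81.7% in replicate 2, although in replicate 1 alone the window before it was higher. Cluster scores on chromosome 4 resembled those of the arms more than those of the Het sequences, with medians of 0.810 in replicate 1 and 1.01 in replicate 2. Accordingly, the mean covered share of chromosome 4 was 12.6% with only the upper 50% of each list by score.

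On the distal parts of the large arms, X had the highest covered share and 3R the lowest. Distal X was covered over 8.47% ± 1.67 and distal 3R over 1.52% ± 0.463 (SD, n = 2), and the distal autosomal arms together over 3.35% ± 0.605 (SD, n = 2). The difference between X and the autosomal arms came with a higher density of clusters. Replicate 1 had 33.0 clusters per Mb of distal X, and 12.6 on 2L, 14.0 on 2R, 13.3 on 3L and 8.36 on 3R. In replicate 2 the densities were 25.8 on X, 9.27 on 2L, 10.2 on 2R, 10.3 on 3L and 5.20 on 3R. Median cluster lengths on distal X, 2232.5 bp in replicate 1 and 2282 bp in replicate 2, lay close to those of distal 2R, 2206.5 bp and 2461.5 bp. On distal 3L they were 2186 bp and 2319 bp. They were shorter on 2L, 2003 bp and 1968 bp, and on 3R, 1965 bp and 2038.5 bp. With the upper 50% of each whole list by score, distal X was covered over 3.17% in replicate 1, 1.22% in replicate 2 and 7.06% in the pooled list, against 1.62%, 1.06% and 2.62% of the distal autosomal arms.

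A few places away from the proximal runs were covered over at least 50% of a 100 kb window in both replicates. On 2L this was the window from 20100001 to 20200000, with 66.2% in replicate 1 and 61.2% in replicate 2. On 2R it was the window from 2100001 to 2200000, with 53.8% and 51.9%, and the window from 2300001 to 2400000, with 65.1% and 61.3%. On X it was the window from 17800001 to 17900000, with 59.7% and 55.8%, and the window from 21600001 to 21700000, with 78.3% and 76.3%. The latter lies 0.723 Mb from the proximal end, so it is part of the proximal 1 Mb of X, where no run began. No window of 3R and no window of 3L outside its proximal run reached this share. These windows were selected after their values were seen.

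The longest pooled cluster touched by both replicates was identified on each arm. On 2R it spanned 96.3 kb from 815223 to 911571, and clusters covered 97.6% of it in replicate 1 and 97.3% in replicate 2. On 3L it spanned 73.8 kb from 23417891 to 23491661 and was covered over 99.8% and 97.5%. On 2L it spanned 67.1 kb from 22576289 to 22643411 and was covered over 99.7% and 99.5%. The longest on X, 53.4 kb from 21758401 to 21811771, was covered over 96.9% and 98.5%. On chromosome 4 it spanned 58.7 kb from 1258994 to 1317701, as 1 cluster in replicate 1 and 4 clusters in replicate 2. The longest on 3R was only 8.58 kb, from 3520969 to 3529545, and it also had the highest pooled score among the distal 3R clusters touched by both replicates.

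The highest-scoring distal clusters touched by both replicates were each a single cluster in both replicates. The cluster on X from 12825776 to 12830061, 4.29 kb long, had a pooled score of 3.17, at percentile 96.5 of the pooled list. The cluster on 2L from 6992596 to 6997257 had a pooled score of 3.13. On 2R the cluster from 9990399 to 9996545 scored 3.10, and on 3L the cluster from 5451199 to 5459993 scored 2.91. Replicate clusters covered between 87.4% and 99.9% of these 4 regions. On chromosome 4, where no proximal window was set apart, the highest-scoring such cluster lay at the left end, from 3 to 5955, with a pooled score of 3.10. The genes at these positions were not analysed here, because the gene table used is of release 6 and the clusters are on release 5.

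The replicates placed their clusters in largely the same regions. The base pair Jaccard index, the shared length divided by the combined length, was 0.858. Rotating replicate 2 within each sequence gave a mean of 0.346 and a highest value of 0.431 (permutation by 1000 rotations, one-sided p = 0.001, the smallest possible). Of the replicate 2 clusters, 94.5% were touched by a replicate 1 cluster over at least 1 bp, and 78.2% of the replicate 1 clusters were touched by replicate 2. The rotation means were 52.7% and 44.1% (permutation by rotation, one-sided p = 0.001 for both). The Jaccard index was 0.949 on the Het sequences, 0.922 on the proximal 1 Mb of the arms, 0.905 on U and 0.799 on chromosome 4. Rotations within these regions, added after the indices were seen, gave means of 0.605, 0.572, 0.588 and 0.319 (permutation by rotation, one-sided p = 0.001 for each). On the distal parts of the 5 arms the index was 0.664 against a rotation mean of 0.0287 within these parts (permutation by rotation, one-sided p = 0.001). Because the index rises with the covered share, it does not rank these regions by agreement. On the distal parts, 90.6% of the replicate 2 clusters but only 64.8% of the replicate 1 clusters were shared.

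The ranking of clusters by score was also similar. Over 2799 pairs of overlapping clusters, Spearman's rho was 0.947 and Pearson's r was 0.936 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give, and adjusted p = 1e-05 over the family of 7 sets of pairs). On the distal parts of the arms, 1170 pairs gave rho = 0.883 and r = 0.931, and on U 860 pairs gave rho = 0.719 and r = 0.722 (permutation p = 1e-05 and adjusted p = 1e-05 for each). The correlations are across regions within these 2 libraries, and regions are not independent replicates.

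**Figure D3:**
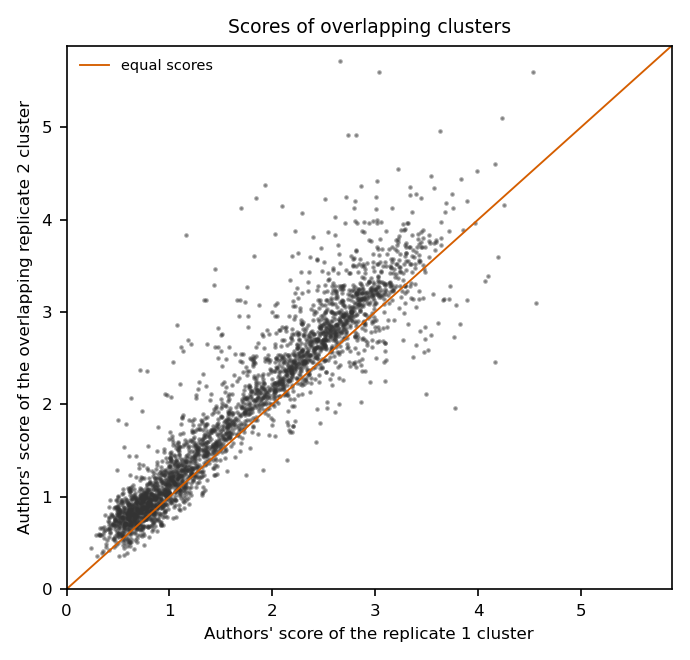
The authors' score of each replicate 1 cluster (horizontal axis) against that of the replicate 2 cluster with the largest overlap (vertical axis), 1 point for each of 2799 pairs, with a line at equal scores. The points follow a single rising trend, with Spearman's rho of 0.947.

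Most pooled clusters were touched by both replicates. Most of those touched by neither lay on the distal arms, which also held most of the pooled list. Of its 4277 clusters, 2337 were touched by both replicates, or 54.6% (95% Wilson interval 53.1 to 56.1%, counting error only). A further 721 were touched by replicate 1 only, 142 by replicate 2 only and 1077 by neither. Of those touched by neither, 308 lay on distal X and 565 on the distal autosomal arms, which held 1047 and 1690 pooled clusters. The share touched by neither was 29.4% and 33.4% there, against 25.2% of the whole list. However, 530 of the 1077, or 49.2%, were shorter than 1301 bp, the length of the shortest cluster in either replicate list, against 555 of all 4277 pooled clusters. Clusters touched by both held 23.7 Mb, and those touched by neither held 1.52 Mb. The share touched by both was 86.9% on U, 79.5% on the Het sequences, 44.2% on distal X and 39.4% on the distal autosomal arms. These shares do not rank the regions by support, because long clusters in densely covered regions are often touched by chance. Clusters touched by both had a median length of 4781 bp and a median score of 1.40, against 1310 bp and 0.505 for those touched by neither. In the upper 50% of the pooled list by score, 84.8% of the clusters were touched by both replicates, and in the lower 50%, 24.5% were.

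**Figure D4:**
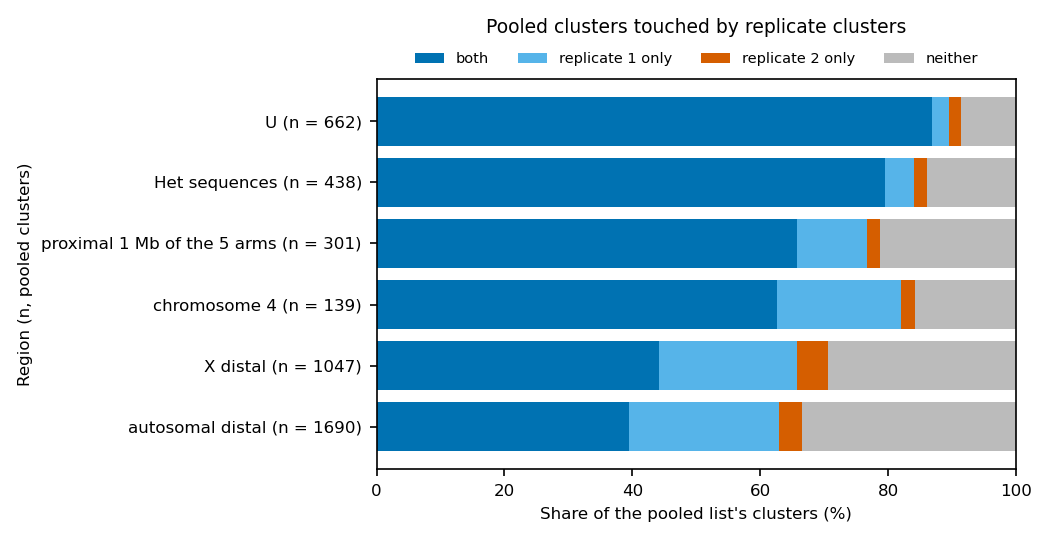
Share of the pooled list's clusters in each region, in percent, that were touched by a cluster of both replicates, of replicate 1 only, of replicate 2 only or of neither, with the number of pooled clusters beside each region. The share touched by both ranges from 39.4% on the distal autosomal arms to 86.9% on U, where touches by chance are also frequent.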

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

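Depth could not be assessed from cluster lists, and no gene-level result was run because no release 5 annotation was used here. The replicate overlap, the score correlations and the proximal to distal ratio kept their direction and stayed past the 0.05 threshold under every alternative run, with ratios between 8.96 (pooled list) and 32.1 (upper 50% of each list by score). Leaving out each arm in turn, an alternative added after the data were seen, gave ratios from 10.7 without 3L to 18.1 without X. With the 3000 highest-scoring clusters of each list, also added later, the Jaccard index was 0.872. The filter on clusters of at least 1 kb removed none and tests nothing. Under a reciprocal overlap of at least 50%, 70.7% of replicate 1 and 78.2% of replicate 2 clusters were shared. Values without a test that moved by more than the replicate SD, or for the pooled support beyond its 95% Wilson interval, are given next for groups of sequences. With the upper 50% of each list by score, the covered share was 3.42% of the autosomal arms, 2.98% of X, 12.6% of chromosome 4 and 70.3% of the Het sequences, so X no longer exceeded the autosomal arms over their whole length. With the pooled list these shares were 7.61%, 14.0%, 58.7% and 79.7%, and U had 82.6%. The ratio of chromosome 4 to the distal arms was 8.24 with the upper 50% by score, 8.90 with the pooled list, 9.10 with a 0.5 Mb window and 14.4 with a 2 Mb window. Merging clusters closer than 1 kb left a mean of 2617 clusters per replicate. Pooled clusters supported by both replicates made up 52.3% when at least 50% of the cluster had to be covered, and 84.8% in the upper 50% by score. Apart from the construction of these settings, the cause was not tested. Leaving out 1 of 2 replicates moves a mean by less than their SD by construction and shows nothing about stability. The autosomal arms and Het sequences taken singly also all moved with the upper 50% by score and with the pooled list, the most in proportion being 3R with 0.246% in the upper 50% by score. No paired analysis was possible because the input libraries have no cluster list of their own.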

Other observations

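In this part, the test of 1 Mb windows, the X to autosome ratio in the upper 50% of the whole lists, the rotation within U, the percentile of the clusters that replicate 1 missed and both tests of cluster length were chosen after the result was seen. The remaining tests were set down after the patterns were noticed but before their values were computed, and for the test of few reads the tied scores had also been seen. Distal X carried clusters in each of its 1 Mb windows, although some of its 100 kb windows held none in either replicate. In 1 Mb windows, the mean covered share of the replicates lay between 3.34% and 12.3% in the 21 windows of distal X, with a median of 8.68%. The 91 distal autosomal windows had a median of 1.96%, and all 21 X windows lay above it. Only 3 autosomal windows exceeded the X median, the highest with 48.3% at the end of the proximal run of 2R. The mean difference was 5.48 percentage points (permutation p = 1e-05, two-sided, the smallest possible, over windows that are not independent replicates). The X to autosome ratio of distal covered share was 2.52 ± 0.0430 (SD, n = 2).

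The weakest clusters alone do not account for the excess on X, since the ratio was 2.91 in replicate 1 and 2.58 in replicate 2 when only the upper 50% of the distal clusters by score was kept. At a stricter cut, the upper 50% of the whole lists, the ratio was 1.95 in replicate 1 and 1.15 in replicate 2 but 2.69 in the pooled list, so a dependence on the threshold stays open. Pericentric heterochromatin reaching far into X would lose the excess once the proximal 4 Mb of every arm were left out, but the ratio then was 3.77 and 4.25. The ratio rose mainly because the autosomal share fell, from 3.78% to 2.45% in replicate 1 and from 2.92% to 1.63% in replicate 2. The X share went from 9.65% to 9.24% and from 7.29% to 6.91%. The distal autosomal share thus includes the parts of the proximal runs that lie beyond 1 Mb. A difference in X dosage between the sexes, X-linked repeats and a biological difference of the X all stay open and were not tested, because no copy number, repeat annotation or sexed sample was used here.

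Replicate 2 had fewer clusters than replicate 1 on the 5 arms, 1610 against 2070, but more on U, 1000 against 906. Of its 1345 distal clusters 90.6% were touched by replicate 1. The 636 of 1806 distal replicate 1 clusters that replicate 2 missed had a median score at percentile 25.2 of their list's distal clusters. These values met the criterion set down beforehand for a stricter effective threshold in replicate 2. However, the 127 of 1345 that replicate 1 missed also lay low, at percentile 26.6 of theirs. A low percentile thus arose in both directions, and the missed shares differ in size. The percentiles therefore cannot show whether replicate 2 had a stricter effective threshold. On U, 97.1% of the replicate 2 clusters were touched by a replicate 1 cluster. Rotation within U gave a mean of 93.1% and a highest value of 97.7% (permutation by rotation, one-sided p = 0.002). The share lay above nearly all rotations, but touching is frequent under rotation too. It therefore cannot show whether the same domains were split into more clusters. There, 165 replicate 1 clusters overlapped 2 or more replicate 2 clusters, and 82 replicate 2 clusters overlapped 2 or more of replicate 1. After clusters closer than 1 kb were merged, U still held 595 clusters in replicate 2 against 516 in replicate 1. Whether the threshold, read depth, the input or the immunoprecipitation differed between the replicates stays open.

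Some high pooled scores lay in clusters that neither replicate called. The highest score of the pooled list, 4.99, belonged to a cluster of 2127 bp on 2R from 15956994 to 15959120 that no replicate cluster touched. Among the 815 distal pooled clusters in the upper 50% of the list by score, 116 were touched by neither replicate, and 42.2% of these had a score that, taken as a log2 value, was a whole number or a fraction with a denominator of at most 3 of a unit found from the tied scores, against 0.594% of the 673 touched by both. The difference of 41.6 percentage points (Fisher's exact test, two-sided p = 9.5e-41) could arise from few reads in the denominator of the count ratio. The test did not limit the numerator, so it says nothing of the number of reads there. For the cluster with the score of 4.99, the ratio was 28 units. The shortest replicate cluster was 1301 bp against 1001 bp in the pooled list, and 55.2% of the 116 were shorter than 1301 bp. These are lengths in the pooled list, and the same place may be shorter in a replicate. The share therefore cannot show whether a length minimum is the whole cause. Among the 52 that were at least 1301 bp long, 32.7% still had such a score, against 0.594% of those touched by both (Fisher's exact test, two-sided p = 1.1e-17). The groups were not matched in length, since those touched by both had a median of 3703 bp. Short length and few reads in the denominator are therefore not separated by this comparison. The unit was also found from scores of the same pooled list.

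The telomeric 100 kb of the 5 arms had a covered share 1.82 times that of the rest of the distal arms in replicate 1 and 1.74 times in replicate 2, but permutation by rotation gave one-sided p = 0.112 and 0.103. The share was 20.5% and 18.4% on X, 20.1% and 11.8% on 3L, 2.13% and 2.15% on 2L, 1.42% and 0% on 3R, and 0% in both replicates on 2R, so the ratio rests on X and 3L.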
